A study of Rattus norvegicus with 8 samples.

How the data were processed

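RNA was extracted with Trizol and sequenced on a BGISEQ-500, per the labels' protocols, from left L4 to L6 dorsal root ganglia taken at day 7, with 4 libraries per group. The labels name the groups control and CPIP. The header of the deposited table calls the comparison group Sham, and its 4 FPKM columns for that group are named Con, which match the control titles. The table gives FPKM per library, made by the authors per the file headers. The genome build is Rnor_6.0, per the submitters' processing notes. The aligner, the counting method, the filters and whether strand was used are not given in the sources used here. The deposited table also holds the authors' log2 fold change, p-value and q-value for CPIP over the group it calls Sham, per the file headers, and the test behind them is not given there. Positions are 1-based, as in the file.

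FPKM divides by transcript length and by the total of mapped fragments, so a transcript that takes a large share of one library lowers all others in it. The fragment totals are not used here, and low values showed no clean steps of single reads that would give the depth, so depth is unknown and no count test or counting interval was run. The 23267 genes of the table include 3305 without values. Of the 19962 with values 5 were at 0 in all 8 libraries. No pair of libraries held identical values (0 pairs), and correlations of log2 values were 0.975 to 0.990 within groups and 0.970 to 0.989 between groups. A current table of rat gene names (assembly GRCr8) held 20695 of the 23267 gene IDs. It served for names and for chromosome names only, and 394 genes have no symbol in the deposited table.

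Values were set to log2(FPKM + 0.5), and the 14739 genes with a mean of at least 0.5 FPKM over the 8 libraries were tested with limma 3.58.1 in R 4.3.3, with a trend of variance on expression and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. Means ± SD are in FPKM. The 38 gene lists, fixed before the data were examined, name 795 symbols, of which 766 were found, 11 of them under another name. Lists with at least 5 measured members (37) were tested with camera at a preset correlation of 0.01 and adjusted over lists, and again with an estimated correlation and with fry. The list of mitochondria-encoded genes had 0 measured members. A median per library is that of log2 values around each gene's mean over the 8 libraries. Exact permutation tests between the groups used all 70 arrangements of the 8 libraries, those of a correlation all 40320 orders, and all are two-sided.

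Genes were named by a rule fixed before the data were examined. It took the 12 higher and 12 lower genes past the threshold with the largest fold change and groups that do not overlap, filled up to 12 with the genes of smallest p and a mean of at least 1 FPKM, which are said not to have passed. It also took up to 4 members of smallest p of each list that passed or held a member past the threshold over all genes or over the list alone. Finally it took 3 members each of 5 lists whatever their result (axon injury, immediate early, cytokine, nociception channel and macrophage genes). Tgoln2, which overlaps Retsat, and Elmod3, between Capg and Retsat, are named for their positions and were chosen after their values were seen.

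The limma step was tested on simulated data with the means and spreads of the 14739 genes of this comparison, 4 against 4, with 200 genes changed in each of 20 draws. It recovered 68.9% of genes changed by 1.5-fold, 88.4% at 2-fold and 93.7% at 4-fold, with 4.76% false calls. The Benjamini-Hochberg cutoff is easier to reach with 200 changed genes than in these data, where 1 gene passed. These shares therefore do not give the power of the comparison made here. In 20 draws with no change the limma step called 1 gene and, in camera, 3 lists in all, with genes drawn independently of each other. Alternatives were a pseudocount of 1 or 0.1, no filter or a mean of at least 1 FPKM, size factors, quantile normalization, no trend, a robust trend, array weights, the replicate number as a block, leaving out each library, and other list tests. Leaving out control 1 and control 2 together, with or without CPIP 3, was chosen after the data were seen. The figures were drawn with matplotlib 3.10.9.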

Results

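Messenger RNA levels were measured in dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of Sprague Dawley rats. The ganglia came from the left lumbar segments L4 to L6, the side opposite the injury, at day 7. The 8 libraries form 2 groups, 4 control libraries and 4 from rats with chronic post-ischemic pain (CPIP), in which a temporary loss of blood flow to a hind paw is used to model the complex regional pain syndrome of type I. Values were deposited as FPKM (fragments per kilobase of transcript, scaled to the fragment total of the library). The sum of FPKM ran from 448795 in CPIP 4 to 483961 in control 4, and 18201 to 18272 genes per library had a value above 0. The number of reads behind these values is unknown. The labels give 1 title per library and do not say which animals or how many contributed to it. The limma and permutation p-values therefore measure the spread between these libraries. Those of camera, the test of gene lists, compare list members with all other genes at a preset correlation. They do not measure how a list varies between libraries.

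The comparison asked which transcripts differ in ganglia contralateral to the injury, in a series whose stated subject is mirror-image pain, pain on the uninjured side. Retsat, which encodes retinol saturase, an enzyme of vitamin A metabolism, fell from 57.4 ± 11.4 FPKM in controls to 19.3 ± 0.917 FPKM in CPIP (SD, n = 4 each). It was the only gene of 14739 tested to pass an adjusted p of 0.05 in limma (adjusted p = 0.0226), with 0 genes higher and 1 lower. Among gene lists fixed before the data were examined, macrophage, complement and interferon-stimulated genes were higher in CPIP, by 1.37-fold, 1.33-fold and 1.15-fold at the list median, and skeletal muscle genes were 8.79-fold lower. Each of these list differences passed camera with a preset correlation and none passed with the correlation estimated from the libraries (adjusted p = 0.68 with an estimated correlation for each of the 4). The skeletal muscle transcripts were concentrated in the libraries control 1 and control 2.

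Retsat lies on chromosome 4 from 100465188 to 100480383 on the plus strand of Rnor_6.0. Its log2 fold change was -1.52 with a standard error of 0.138, a 2.87-fold lower level. The CPIP libraries held 18.02 to 20.16 FPKM and the controls 64.21, 61.54, 63.44 and 40.41 FPKM, so the groups did not overlap. The adjusted p passed 0.05 without control 4 (1.29e-05) or CPIP 2 (0.0486) and missed it without control 1 (0.127), control 2 (0.0542), control 3 (0.143), CPIP 1 (0.0777), CPIP 3 (0.132) or CPIP 4 (0.166), while the log2 fold change in these 6 settings stayed between -1.53 and -1.46. It also missed 0.05 with no filter on low values (0.0555) and with no trend of variance on expression (0.0666). Without control 1 and control 2, a choice made after the data were seen, 0 genes were higher and 1 lower, LOC100910177, and Retsat had a log2 fold change of -1.37 (SE 0.161, adjusted p = 0.311). Retsat overlaps Tgoln2 on the opposite strand, and whether the authors' counting used strand is not given in the sources used here. Tgoln2 itself differed by -0.05 log2 (SE 0.0505).

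Capg, which encodes an actin filament capping protein, lies 45069 bp upstream of Retsat, at 100395693 to 100420118 on the same strand. Its level was 40.0 ± 11.0 FPKM in controls and 14.5 ± 5.40 FPKM in CPIP (SD, n = 4 each), a log2 fold change of -1.46 with a standard error of 0.264, and the groups did not overlap. Elmod3, which lies between Capg and Retsat, differed by 0.08 log2 (SE 0.104). Capg did not pass over all genes (limma adjusted p = 0.632). The 15 other tested genes whose starts lay within 500000 bp of the middle of the pair differed by -0.23 to 0.09 log2.

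**Figure D1:**
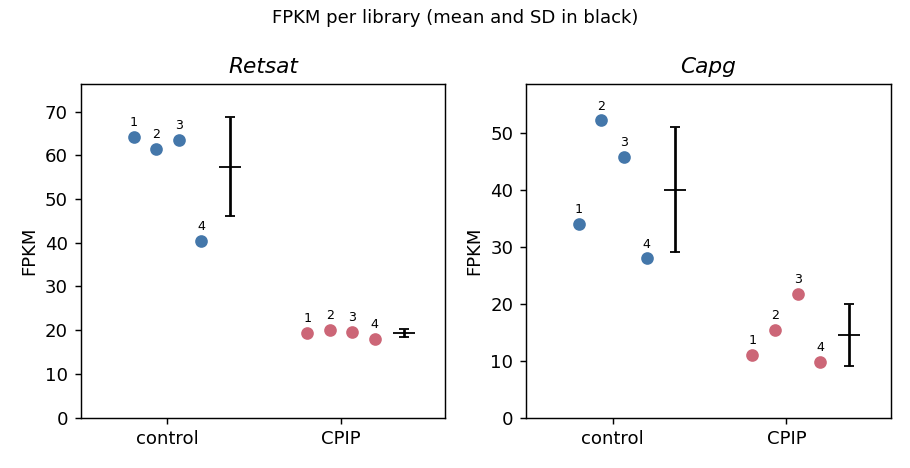
FPKM of Retsat and Capg in each of the 4 control and 4 CPIP libraries, with replicate numbers above the points and the mean and SD of each group in black. Control 4, at 40.41 FPKM for Retsat and 27.98 FPKM for Capg, is the lowest control for both genes, and every CPIP library lies below it.

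**Figure D2:**
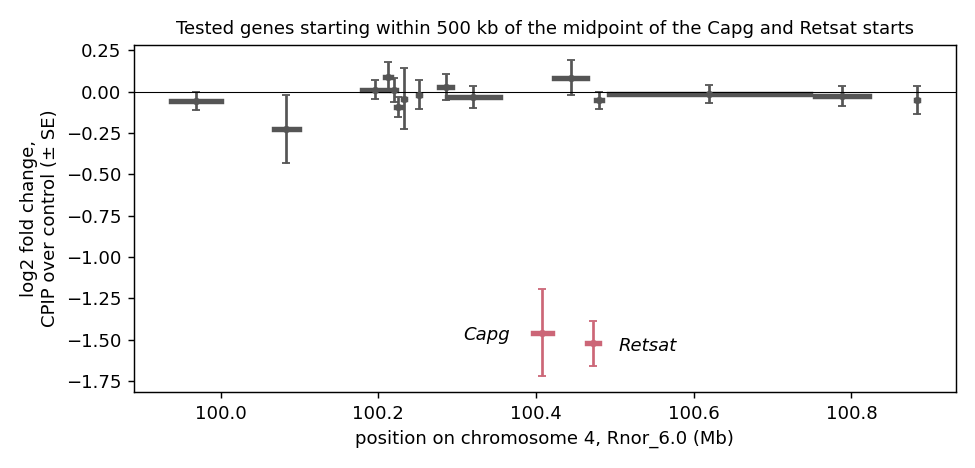
Log2 fold change of CPIP over control (vertical axis, bars are the standard error) against position on chromosome 4 in Mb for 17 tested genes, each horizontal line spanning a gene. Capg and Retsat lie near -1.5 and the 15 others between -0.23 and 0.09.

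Of the 14739 genes, 1152 (7.82%) had an unadjusted limma p under 0.05, 715 higher and 437 lower in CPIP, and after Retsat the smallest adjusted p was 0.632. The 4 values of each group lay apart in 649 genes (4.40%, against 2.86% by chance for a single gene), 408 higher and 241 lower. Genes vary together and the share was not computed for other groupings of the libraries, so this excess cannot exclude chance. The values that follow belong to genes that did not pass. Among those of smallest p, Gabra3, a subunit of the inhibitory GABA-A receptor, was at 8.36 ± 0.719 FPKM in controls and 11.0 ± 0.965 in CPIP (log2 0.38, SE 0.0816). Slfn5 of the schlafen family was at 8.99 ± 0.735 and 12.3 ± 1.29 FPKM (log2 0.43, SE 0.0885), Samd9l at 4.11 ± 0.419 and 5.42 ± 0.231 (log2 0.36, SE 0.0802), and Skap2, an adaptor protein of immune cells, at 5.66 ± 0.515 and 8.04 ± 1.03 (log2 0.47, SE 0.0988). Others on the higher side were LOC100363289 (log2 0.64), Tti1 (0.29), LOC102547811 (0.59), Stk32b (0.73), Cygb (0.22), LOC688637 (0.28), Prkd3 (0.32) and Sned1 (0.65). On the lower side Adamts8, a secreted metalloprotease, was at 4.79 ± 0.726 FPKM in controls and 2.73 ± 0.397 in CPIP (log2 -0.71, SE 0.125). Ndufaf8, an assembly factor of respiratory complex I, was at 20.4 ± 1.34 and 16.2 ± 0.626 FPKM (log2 -0.33, SE 0.0580). The others were LOC100911372 (log2 -0.66), LOC102552640 (-0.54), Ankrd13d (-0.21), Acot7 (-0.20), NEWGENE_621802 (-0.47), Hoxd1 (-0.23), Tubg1 (-0.25) and LOC690468 (-2.82), a ribosomal protein pseudogene in the current annotation whose reads may be shared with near-identical copies. All 12 genes named on each side had groups that did not overlap.

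Macrophage markers rose as a list, with 20 of 20 measured members above control, a median of 0.45 log2 and a camera adjusted p of 1.2e-07 (adjusted p = 0.68 with an estimated correlation). No member passed over all genes and 0 passed adjusted over the list alone. The mannose receptor gene Mrc1 was at 3.50 ± 0.423 FPKM in controls and 5.01 ± 0.837 in CPIP (log2 0.46, SE 0.120), Csf1r, the receptor for macrophage colony-stimulating factor, at 10.4 ± 2.53 and 15.2 ± 2.81 (log2 0.55, SE 0.180), the protease gene Ctss at 16.2 ± 3.69 and 22.8 ± 3.33 (log2 0.50, SE 0.160) and Adgre1 at 2.86 ± 0.950 and 5.18 ± 1.85 (log2 0.75, SE 0.262). Complement genes rose as a list, with 19 of 23 members above control, a median of 0.41 log2 and an adjusted p of 8.39e-05 (adjusted p = 0.68 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. C1s was at 19.8 ± 6.84 and 37.1 ± 13.6 FPKM (log2 0.89, SE 0.281) and C2 at 6.56 ± 1.34 and 11.3 ± 4.01 (log2 0.71, SE 0.221), and the receptor genes C3ar1 and C5ar1 differed by 0.81 and 0.41 log2. The library medians of both lists were highest in CPIP 3, at 0.82 for macrophage and 0.85 for complement genes, and lowest in control 1 and control 2. With CPIP 3 left out the list medians were 0.28 and 0.21 log2, both lists still past 0.05 (adjusted p = 6.36e-05 and 0.00147). Without control 1 and control 2 the medians were 0.31 and 0.24 log2 (adjusted p = 0.000549 and 0.00158), and without these and CPIP 3 they were 0.09 and 0.12 (0.171 and 0.0475). In an exact permutation test of the 8 library medians (two-sided, 70 arrangements, smallest possible p 0.0286) p was 0.114 for macrophage markers and 0.0571 for complement genes, and 0.333 for both after adjustment over 14 lists.

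Interferon-stimulated genes rose as a list, with 34 of 36 members above control, a median of 0.20 log2 and a camera adjusted p of 2.24e-06 (adjusted p = 0.68 with an estimated correlation). Over all genes and adjusted over the list alone 0 members passed. Herc6 was at 1.75 ± 0.217 FPKM in controls and 2.33 ± 0.220 in CPIP (log2 0.33, SE 0.102), the transcription factor gene Irf1 at 4.43 ± 0.818 and 5.86 ± 0.546 (log2 0.38, SE 0.119), and Ifi47 at 3.93 ± 0.915 and 5.49 ± 0.698 (log2 0.45, SE 0.149). Without control 1 and control 2 the list median was 0.18 log2 (camera adjusted p = 3.21e-13). Control 2 held the highest control median, 0.11 log2, above CPIP 2, CPIP 3 and CPIP 4 (0.04, 0.07 and 0.10). Leaving out control 2 alone gave a list median of 0.26 log2 (camera adjusted p = 3.22e-14), and control 1 alone 0.15 (5.87e-05). The exact permutation p of the library medians of this list was 0.114 (0.333 adjusted over 14 lists). Cytokines and chemokines had 17 of 21 members above control, a median of 0.19 log2 and an adjusted p of 0.0128 (adjusted p = 0.68 with an estimated correlation), 0 of them past adjusted over the list alone. The chemokine genes Ccl7, Ccl6 and Cxcl13 differed by 0.83, 0.56 and 1.05 log2. Fibroblast and extracellular matrix genes had 22 of 26 members above control, a median of 0.26 log2 and an adjusted p of 0.0128 (adjusted p = 0.681 with an estimated correlation), also with 0 past adjusted over the list alone. The proteoglycan genes Dcn and Lum were at 354 ± 121 and 600 ± 107 FPKM (log2 0.81, SE 0.239) and at 71.7 ± 21.5 and 115 ± 27.9 (log2 0.70, SE 0.228), Pdgfra differed by 0.47 log2 and Pi16 by -0.78. Without control 1 and control 2 neither the cytokine list (adjusted p = 0.247) nor the fibroblast list (0.127) passed, and without CPIP 3 alone their medians were 0.10 and 0.13 log2 (adjusted p = 0.0849 and 0.311).

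Skeletal muscle genes fell as a list, with 15 of 15 members below control, a median of -3.14 log2 and a camera adjusted p of 3.08e-13 (adjusted p = 0.68 with an estimated correlation). Over all genes 0 members passed and 13 passed adjusted over the list alone. This count was 0 without control 1, control 2, CPIP 1, CPIP 2 or CPIP 3. It was 9 without CPIP 4 and 15 without control 3 or control 4. Mylpf, a myosin light chain gene, was at 92.21, 255.88, 8.34 and 3.49 FPKM in controls 1 to 4 and at 2.24, 0.80, 0.99 and 4.84 FPKM in CPIP 1 to 4. Myl1, Tnnc2 and the creatine kinase gene Ckm reached 254.8, 198.84 and 236.09 FPKM in control 2, and their log2 fold changes were -4.34 (SE 1.29), -4.15 (SE 1.22) and -3.76 (SE 1.26). All 15 members were higher in both control 1 and control 2 than in each of the other 6 libraries. The list median was -2.59 log2 without control 1, -2.32 without control 2 and -4.175 without control 4. Without both control 1 and control 2 it was -0.96 log2. The first principal component of all tested genes held 34.4% of the variance, with scores of -24.7 and -34.9 for control 1 and control 2 and 1.51 to 16.7 for the other 6. The list medians of the controls were 3.30, 4.92, -0.11 and -1.13 log2 around the mean of the 8 libraries, and those of CPIP lay between -2.11 and -0.65 (exact permutation p = 0.0571, and 0.333 adjusted over 14 lists).

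**Figure D3:**
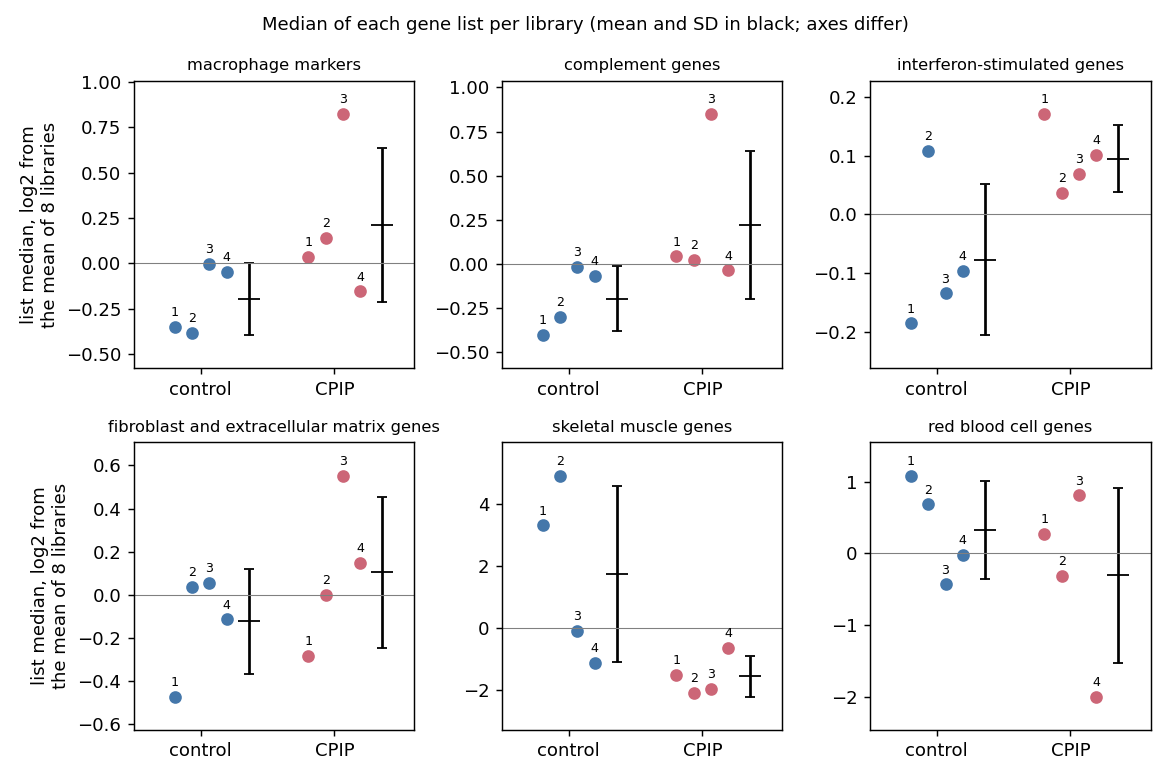
Median of 6 gene lists in each of the 4 control and 4 CPIP libraries, in log2 from each gene's mean over the 8 libraries, with replicate numbers above the points and the group mean and SD in black. The macrophage and complement medians are highest in CPIP 3 (0.82 and 0.85), and the skeletal muscle medians are highest in control 1 (3.30) and control 2 (4.92). The vertical axes differ between panels.

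Further lists fell with camera, and none did so with an estimated correlation, where their adjusted p was 0.68 to 0.681. Mural and smooth muscle markers had 13 of 13 members below control and a median of -0.32 log2 (adjusted p = 0.000446), which without control 2 was -0.10 (adjusted p = 0.0507), with Acta2 at 45.67 FPKM in control 2 and 13.29 to 24.8 in the other 7 libraries, and Des, Notch3 and Lmod1 at -1.36, -0.17 and -0.37 log2. Cartilage, bone and epithelium genes had 9 of 9 below control (median -0.32, adjusted p = 0.000475), with the bone genes Bglap and Ibsp at 53.18 and 12.06 FPKM in control 2 and Alpl at -0.23 log2, and 1 member, the keratin gene Krt8, past adjusted over the list alone (3.52 ± 0.347 and 2.72 ± 0.179 FPKM). With each library left out in turn Krt8 kept this call in 1 of 8 fits (0.0409 to 0.141). Leaving out control 2 brought the median of this list to -0.04 (adjusted p = 0.105). Red blood cell genes had 11 of 13 below control (median -0.65, adjusted p = 0.00227), but without CPIP 4 the median was -0.08 (adjusted p = 0.23). The alpha-globin gene Hba-a1, whose reads near-identical copies may share, was listed at 31.5, 9.41, 0 and 4.99 FPKM in the controls and at 0, 0, 0.15 and 1.18 in CPIP. The other red cell genes LOC689064, Slc4a1 and Epb42 differed by -0.71, -0.72 and -0.23 log2. Neutrophil and mast cell markers had 10 of 13 below control (median -0.80, adjusted p = 0.0276), and here too the median was small without CPIP 4 (-0.10, adjusted p = 0.317). Their granule genes Ngp, Camp and Elane were at -1.03, -1.27 and -0.90 log2 and the mast cell gene Cpa3 at 0.98. Vascular endothelial markers had 12 of 15 below control (median -0.05, adjusted p = 0.0345), which missed 0.05 in 5 of the 8 fits with 1 library left out and had a median of -0.02 without CPIP 4 (adjusted p = 0.0745), with Cldn5, Vwf and Plvap at -0.24, -0.32 and -0.62 log2 and Cdh5 at 0.23. Nuclear oxidative phosphorylation genes had 24 of 27 below control (median -0.06, adjusted p = 0.000394), Uqcrc1, Ndufv1, Atp5mc1 and Ndufb3 among them at -0.13, -0.10, -0.13 and -0.13 log2. Cholesterol synthesis genes had 15 of 20 below control (median -0.03, adjusted p = 0.0306), with Dhcr7, Mvd and Insig1 at -0.18, -0.20 and -0.10 log2 and Hsd17b7 at 0.19. Without control 1 and control 2 only the last 2 of these 7 lists passed (adjusted p = 2.69e-07 and 0.000136), and the others had adjusted p of 0.227 to 0.536. Those 2 lists missed 0.05 without control 4, where the medians were -0.04 and -0.01 log2 (adjusted p = 0.0614 and 0.505), and without CPIP 4 the medians were -0.01 and -0.02 (0.038 and 0.0457). Apart from Krt8, 0 members of these lists passed adjusted over the list alone, and 0 passed over all genes.

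Of the lists on sensory neurons, potassium channels fell with camera, with 25 of 32 members below control and a median of -0.08 log2 (adjusted p = 0.00227; adjusted p = 0.681 with an estimated correlation), and not without control 1 and control 2 (median -0.03, adjusted p = 0.228), control 1 alone (-0.04, 0.119) or CPIP 3 (-0.05, 0.0552). Kcnn1 was at 9.24 ± 0.963 FPKM in controls and 7.43 ± 1.26 in CPIP (log2 -0.30, SE 0.119), and Kcnt1, Kcnd1 and Kcnc4 differed by -0.12, -0.11 and -0.10 log2. Nociception-related cation channels did not pass (median -0.02, adjusted p = 0.0789), but did so, lower in CPIP, without control 2 (0.0247), control 4 (0.0297) or CPIP 4 (0.00897). Hcn2 differed by -0.18 log2 and the purinergic receptor gene P2rx7 by 0.32. Axon injury and regeneration genes had a median of 0.0016 log2, a mean of -0.03 and a test direction below control (adjusted p = 0.357). Their members of smallest p were Tubb2b, Crh and Basp1, at -0.12, -0.65 and -0.26 log2. Immediate early genes had a median of -0.02, a mean of 0.04 and a test direction below control (adjusted p = 0.673), with Klf2, Atf3 and Dusp1 at -0.49, 0.45 and -0.40 log2. Inhibitory and opioid-related receptors did not pass (median 0.00066, adjusted p = 0.519), but Gabra3 passed adjusted over the list alone (in 3 of 8 fits with 1 library left out), beside Sstr2, Npy1r and Gabbr2 at -0.37, -0.26 and -0.09 log2. Peptidergic nociceptor markers (median -0.10, adjusted p = 0.0734), non-peptidergic and pruriceptor neuron markers (0.0048, 0.673), large-diameter neuron markers (-0.07, 0.0857), glutamate and excitatory transmission genes (-0.02, 0.161) and neurotrophin and GDNF family genes (0.03, 0.809) did not pass. In the lists of this paragraph 0 members passed over all genes, and apart from Gabra3 0 passed adjusted over the list alone.

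Circadian clock genes did not pass as a list (median 0.16 log2, adjusted p = 0.0734), but 2 members passed adjusted over the list alone. Nfil3, a repressor of clock output genes, was at 2.76 ± 0.357 FPKM in controls and 1.84 ± 0.333 in CPIP (log2 -0.48, SE 0.125), and Nr1d2, a nuclear receptor of the clock, at 12.4 ± 0.705 and 14.7 ± 1.03 (log2 0.24, SE 0.0654). With each library left out in turn Nfil3 kept this call in 2 of 8 fits and Nr1d2 in 1 of 8. Per3 and Per2 were at 0.29 and 0.34 log2. The glial lists did not pass, with medians of 0.01 log2 for satellite glial cell markers (adjusted p = 0.78, test direction flipped under quantile scaling) and 0.11 for myelinating Schwann cell genes (adjusted p = 0.0638). Neither did T, B and NK cell markers (-0.10, adjusted p = 0.44), MHC class I and II genes (0.14, 0.0734), matrix metalloproteinases and inhibitors (0.09, 0.644), spinal cord and oligodendrocyte markers (0.12, 0.785) or adipocyte genes (-0.13, 0.0638). The stress and growth lists gave medians of 0.03 for hypoxia-responsive genes (adjusted p = 0.876, test direction flipped under quantile scaling), -0.03 for oxidative stress response genes (0.581), -0.13 for glucocorticoid-responsive genes (0.091), -0.02 for heat shock genes (0.243), 0.0031 for cytosolic ribosomal protein genes (0.769, test direction flipped under quantile scaling) and -0.07 for cell proliferation genes (0.0632). In these lists other than the clock genes 0 members passed adjusted over the list alone. Without control 1 and control 2 the circadian clock genes passed as a list, higher in CPIP (adjusted p = 0.000186). In 8 of the 37 lists tested the median, mean and test direction did not share a sign, none of them a list that passed. Besides axon injury and immediate early genes these were the lists of non-peptidergic neurons, satellite glia, hypoxia and ribosomal proteins (median and mean above 0, test direction below control), inhibitory receptors (median alone above 0) and oxidative stress (mean alone above 0).

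In the authors' deposited table, 5476 of 19044 genes with a q-value were at 0.05 or less, 3274 higher and 2202 lower in CPIP, and 462 of them (173 higher, 289 lower) also had a log2 fold change of at least 1 in size. Whether the q-values of the authors' deposited table take the spread between libraries into account is not given in the sources used here. For Capg the authors' q was 5.67e-261, where limma on the 8 libraries gave an unadjusted p of 0.000372. For Mylpf, Ckm, Myl1 and Tnnc2 the authors' q is listed as 0, and the unadjusted limma p was 0.00781 to 0.0155. For these genes the values argue against a test that uses that spread. Of those 5476 genes, 5077 were tested with limma, 1110 had an unadjusted limma p under 0.05 and 1, Retsat, passed after adjustment. The authors' deposited table gives Retsat a log2 fold change of -1.57 and Capg -1.46. The 462 genes with the larger fold changes included 166 tested here, of which 68 had an unadjusted limma p under 0.05 (19 higher, 49 lower) and 17 had groups that did not overlap. The authors' deposited table gives -5.34 for Mylpf and -5.51 for Ckm, the muscle genes high in control 1 and control 2.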

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

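The tests of control 1 and control 2 on the immune lists, the share of neurons, the whole-cause test of the muscle genes and all tests on Retsat and Capg were chosen after the results were seen, and the second muscle list, the removal of CPIP 3 and the splits of the libraries were fixed before theirs.

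Other splits of the 8 libraries into 4 and 4 bear on every count in the report. The real split gave 1 gene, 13 of the 35 splits gave at least as many and the highest other gave 2, so chance cannot be excluded. It gave 14 lists, 18 of the 35 splits gave at least as many and the highest other gave 21, which points to structure among the libraries that the groups do not follow. List by list, the real split alone, 1 of 35, gave a camera p as small for complement genes (9.07e-06, smallest other 7.07e-05), but this is the lowest share that 35 splits can give and 14 lists were examined, so chance is not excluded there. It could not be excluded either for skeletal muscle genes (2 of 35 splits; p 8.31e-15, smallest other 9.57e-16), macrophage markers (3; 6.47e-09, other 1.74e-11), cartilage, bone and epithelium genes (3; 8.99e-05, other 1.09e-05), interferon-stimulated genes (5; 1.82e-07, other 3.31e-17), cytokines (6; 0.00363, other 0.000239), mural markers (6; 7.24e-05, other 2.87e-09), endothelial markers (7; 0.013, other 4.36e-05), potassium channels (10; 0.000525, other 1.01e-09), oxidative phosphorylation genes (11; 5.32e-05, other 8.08e-14), cholesterol synthesis genes (12; 0.0108, other 4.82e-08), neutrophil and mast cell markers (14; 0.00895, other 1.17e-12), fibroblast genes (14; 0.0038, other 1.44e-13) and red blood cell genes (14; 0.000553, other 2.78e-14).

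Retsat and Capg, which lie 45069 bp apart on chromosome 4 with the gene Elmod3 (0.08 log2) between them, were both lower in CPIP, and Retsat in control 4 stood apart from the other controls (40.41 FPKM against 61.54 to 64.21). The authors' scaling as the cause is argued against, because size factors or quantiles moved either fold change by at most 0.0155 log2. Reads from muscle are argued against as well, because control 3, whose muscle median was 5.03 log2 below that of control 2, differed from control 2 by at most 0.187 log2 in either gene. An inherited variant near the pair remains a candidate explanation: control 4 lay at 0.482 of the way from the CPIP mean to the mean of controls 1 to 3 for Retsat and at 0.457 for Capg, a difference of 0.0254, as a carrier of 1 low and 1 high copy might, but Capg ran from 34.04 to 52.2 FPKM in controls 1 to 3, so 27.98 in control 4 is not set apart there. In CPIP Capg ran from 9.86 to 21.78 FPKM and Retsat from 18.02 to 20.16, so the low group was less uniform for Capg. The reading as a carrier needs 1 rat per library, and the labels do not say how many animals contributed to each. All CPIP libraries were low and no genotype was examined, so an inherited variant cannot be told apart from an effect of CPIP on both genes.

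Skeletal muscle genes were lower in CPIP mainly because control 1 and control 2 were high. Muscle tissue carried into these libraries may be the source. Of a second list of 23 muscle genes, 18 were measured and 15 (83.3%) were higher in both than in each of the other 6 libraries. For a single gene chance gives 3.57%, but muscle genes vary together (estimated correlation 0.967 in the first list). All 15 genes of the first list were already higher in both libraries, so the second list is not independent support. Mylpf reached 255.88 FPKM in control 2. Of the first list's 15 genes, 10 had a mean of at least 0.5 FPKM in CPIP and 0 are in another list. A lower level in ganglion cells after CPIP as the whole cause is argued against, because the list medians of the 4 controls ranged over 6.05 log2 and the groups differed by -3.31. A smaller difference remains open. Without control 1 and control 2 the median was -0.96 log2 (camera adjusted p = 3.06e-09). That p assumes the preset correlation, so it cannot decide the question for genes that vary together this closely. The library medians overlapped, with control 3 at -0.11 log2, control 4 at -1.13 and CPIP 4 at -0.65. The other CPIP libraries lay lower, at -2.11 to -1.53.

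Macrophage, complement and interferon-stimulated lists were higher in CPIP with camera, every value of which assumes the preset correlation, and an immune response to CPIP stays open. These camera calls held without control 1 and control 2, which were high in muscle transcripts. There the larger adjusted p of macrophage and complement was 0.00158 and that of interferon-stimulated genes 3.21e-13. For interferon-stimulated genes this left out control 2, whose list median (0.11 log2) was the highest of the controls. Without CPIP 3 alone the calls held too (0.00147 and 2.89e-06). Camera gave at least as many lists as the real groups in 18 of the 35 splits. A kept call therefore cannot exclude these libraries as a cause. The macrophage and complement medians were then 0.31 and 0.24 log2 without those controls, 0.28 and 0.21 without CPIP 3, and 0.09 (adjusted p = 0.171) and 0.12 (0.0475) without all 3, so most of both rises could rest on these libraries jointly. A lower share of neurons as the whole cause would raise all other cell types alike. Beside 0.45 log2 for macrophage markers the medians were 0.01 for satellite glial (SD of the members 0.152) and 0.11 for Schwann genes (0.0891). They were -0.05 for endothelial (0.198) and -0.32 for mural genes (0.374), so 4 of 5 lists lay lower by more than that SD. Fibroblast genes (0.26, SD 0.429) did not. This comparison of members was added after the permutation test below had missed its bound. List members share the same libraries, so it cannot decide the question. Over the libraries the difference of macrophage from satellite glial medians was 0.393 log2 (exact permutation p = 0.229). That from the mean of the 5 lists was 0.409 (exact permutation p = 0.0857). Both missed 0.05, the bound first set for this test. A lower share of neurons, as the whole cause or a part, therefore cannot be told apart from more macrophages.

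In 18 of 268 groups of 4 libraries 1 library stood far from the other 3, where chance gives about 1 in 20, or 13.4. The sum of FPKM was 484000 in control 4 against 469200 to 471500. Slfn5 was at 7.90 FPKM in control 2 (others 9.22 to 9.49), Samd9l at 5.76 in CPIP 1 (5.25 to 5.33), and the pseudogene LOC690468 at 2.71 in CPIP 2 (0 to 0.06). Acot7 was at 246.1 in control 3 (261.1 to 263.9) and 234.3 in CPIP 2 (221.6 to 222.8), and Tubg1 at 42.0 in control 1 (46.2 to 46.88). Cxcl13 and C3ar1 were at 13.88 and 2.38 FPKM in CPIP 3 (others 3.25 to 4.70 and 1.12 to 1.28). Hba-a1 was at 1.18 in CPIP 4 (0 to 0.15) and Ibsp at 1.68 in CPIP 2 (1.22 to 1.26). Among list medians, immediate early genes stood apart in control 4 (-0.28 log2, others 0.08 to 0.13) and in CPIP 4 (0.60, others -0.26 to -0.19), potassium channels in control 1 (0.15, others -0.0038 to 0.01) and complement genes in CPIP 3 (0.85, others -0.04 to 0.04). Spinal cord and oligodendrocyte markers stood apart in control 4 (0.19, others -0.09 to -0.06), and cartilage, bone and epithelium genes in control 2 (1.59, others -0.21 to 0.0085).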

How the results depend on the processing

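Leaving out control 1 and control 2 together, with or without CPIP 3, was chosen after the data were seen, and all other alternatives before. The cause of a changed value was not tested, except that leaving out libraries leaves fewer samples. Retsat kept its direction in 20 of 20 alternatives and passed 0.05 in 9 of them, with adjusted p from 1.29e-05 to 0.38. The count of lower genes, 1 in the report, was 0 with no filter and 0 with no trend. It ran from 0 to 2 over the libraries left out one at a time (2 without control 2 or CPIP 2, 0 without control 1, control 3, CPIP 1, CPIP 3 or CPIP 4), and that of higher genes from 0 to 1 (1 without control 4, CPIP 1 or CPIP 2). The genes gained, LOC100910177, LOC679565, RGD1359290, Tsr2, LOC100910581 and LOC690468, were noted after their values were seen. With control 1 and control 2 left out the lower gene was LOC100910177, and Retsat had an adjusted p of 0.311. Without these and CPIP 3 there were 2 higher genes (LOC100362027 and LOC100909548) and 2 lower (LOC100360828 and LOC100910177), and Gabbr2 turned to a log2 fold change of 0.012. Of the 96 named genes only Retsat had a call to lose.

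The replicate numbers showed no clear pairing of the libraries. Deviations of same-numbered libraries correlated by 0.0953, -0.0371, 0.0565 and -0.00885, and those of different-numbered libraries by -0.134 to 0.0433. Of the 8 libraries 4 correlated best with their own number, so a weak pairing cannot be excluded. With the replicate number as a block 0 genes were lower (Retsat adjusted p = 0.0745), 7 lists higher and 11 lower, and the 14 list calls were kept.

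With an estimated correlation and with fry 0 lists were higher and 0 lower. The estimated correlation gave adjusted p of 0.68 or 0.681 for the 14 lists. With fry the values were 0.657 for macrophage, complement, interferon-stimulated, cytokine and skeletal muscle genes, 0.659 for cartilage, bone and epithelium genes and 0.76 for the other 8. With no filter the adjusted p of both neutrophil and mast cell markers and vascular endothelial markers was 0.0514, and with size factors these were 0.0582 and 0.0516. Cholesterol synthesis genes missed 0.05 with quantiles (0.15) and array weights (0.101), which also ended the calls for cytokines and chemokines (0.0594) and for fibroblast and extracellular matrix genes (0.101). The robust trend has no list test and gave no list values. At a mean of at least 1 FPKM the lists of T, B and NK cell and of spinal cord and oligodendrocyte markers had too few members to test. Leaving out control 1 and control 2 left 4 lists higher and 3 lower, and adjusted p was 0.228 for potassium channels, 0.366 for neutrophil, 0.247 for cytokine, 0.127 for fibroblast, 0.536 for endothelial, 0.361 for mural, 0.387 for red blood cell and 0.227 for cartilage, bone and epithelium genes. Without these and CPIP 3, 3 lists were higher and 8 lower, among the latter axon injury (0.0071), ribosomal protein (0.00134) and cell proliferation genes (0.00873), which had not passed with all libraries. There adjusted p was 0.171 for macrophage, 0.939 for potassium channel and for fibroblast, 0.54 for cytokine, 0.548 for endothelial, 0.0962 for mural and 0.152 for cartilage, bone and epithelium genes.

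With each library left out in turn, 3 to 7 lists were higher (3 without control 1) and 6 to 12 lower. The adjusted p stayed under 0.05 for skeletal muscle (1.31e-19 to 2.39e-09), interferon-stimulated (3.22e-14 to 0.000436), macrophage (3.11e-11 to 6.36e-05) and complement genes (1.88e-05 to 0.00147). Potassium channels ran from 2.97e-06 to 0.119 (over 0.05 without control 1 or CPIP 3), cytokines from 0.00151 to 0.0854 (control 1, CPIP 3), fibroblast genes from 0.000146 to 0.311 (control 1, CPIP 3, CPIP 4), mural markers from 2.35e-06 to 0.0507 (control 2), and cartilage, bone and epithelium genes from 5.57e-05 to 0.105 (control 2). Red blood cell genes ran from 4.33e-06 to 0.23 (CPIP 4), oxidative phosphorylation genes from 2.1e-07 to 0.0614 (control 4), cholesterol synthesis genes from 0.00122 to 0.505 (control 4, CPIP 1, CPIP 3), endothelial markers from 0.00552 to 0.132 (control 1, control 2, control 3, CPIP 2, CPIP 4) and neutrophil and mast cell markers from 9.38e-05 to 0.317 (control 1, control 2, control 3, CPIP 1, CPIP 4).

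Lists that had not passed with all libraries did so, without turning direction, in some settings, at a lowest adjusted p of 4.33e-06 for cell proliferation, 0.000104 for circadian clock, 0.000173 for immediate early, 0.000475 for large-diameter neuron, 0.00134 for myelinating Schwann cell, 0.00135 for MHC, 0.00579 for glucocorticoid-responsive, 0.0071 for axon injury, 0.00763 for adipocyte, 0.00897 for nociception channel, 0.0181 for glutamate, 0.0295 for peptidergic neuron and 0.0466 for heat shock genes. Array weights also passed the nociception channel and large-diameter neuron lists (both 0.034).

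Lists that had not passed turned direction in some settings. With single libraries left out their adjusted p ran from 0.000173 to 0.927 for immediate early genes, 0.132 to 0.927 for non-peptidergic neuron, 0.0745 to 0.933 for inhibitory receptor, 0.449 to 0.971 for neurotrophin and GDNF family genes, 0.137 to 0.996 for satellite glial cell markers, 0.00134 to 0.602 for myelinating Schwann cell genes, 0.152 to 0.891 for T, B and NK cell markers, 0.19 to 0.954 for matrix metalloproteinases and inhibitors, 0.485 to 0.967 for spinal cord, 0.494 to 0.991 for hypoxia-responsive genes and 7.04e-06 to 0.616 for cytosolic ribosomal protein genes, the last turned and past 0.05 without CPIP 4. Turned values were 0.915 for T, B and NK cell and 0.473 for spinal cord genes with no filter, 0.729 for satellite glial, 0.97 for hypoxia and 0.151 for ribosomal protein genes with quantiles, and 0.75 for neurotrophin, 0.886 for metalloproteinase and 0.265 for ribosomal protein genes with array weights. With fry they were 0.994 for inhibitory receptor and for ribosomal protein, 0.968 for satellite glial and 0.948 for hypoxia genes. With control 1 and control 2 left out they were 0.351 for immediate early, 0.669 for Schwann cell and 0.467 for T, B and NK cell genes. Without these and CPIP 3 they were 0.146 for immediate early, 0.887 for large-diameter neuron, 0.939 for inhibitory receptor, 0.98 for glutamate, 0.447 for Schwann cell, 0.955 for T, B and NK cell and for hypoxia, 0.835 for metalloproteinase and 0.577 for glucocorticoid-responsive genes. Depth is unknown, so what it limits could not be measured.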

Other observations

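The test of the clock genes was chosen after their values were seen.

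Immediate early genes, which neurons switch on within minutes of activity, varied between libraries of 1 group more than between groups. Their list median was 0.60 log2 above the mean of the 8 libraries in CPIP 4 and -0.19 to -0.26 in the other CPIP libraries, and it was -0.28 in control 4 against 0.08 to 0.13 in the other controls. CPIP 4 also held the lowest red blood cell median (-2.00 log2) and the lowest neutrophil and mast cell median (-1.71), and control 1 the lowest myelinating Schwann cell median (-0.46). CPIP 3 held the highest fibroblast median (0.55) beside its macrophage and complement medians.

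A different time of day at tissue collection between libraries was examined as a hypothesis for Nfil3, Nr1d2 and Per3. Over the 8 libraries the mean of Nr1d1, Dbp, Tef, Per3 and Ciart and the mean of Arntl, Npas2 and Cry1, which peak at opposite times of day, had a Pearson r of -0.705 (exact permutation p = 0.0448) and a Spearman rho of -0.571 (exact permutation p = 0.151). After adjustment over these 2 values p was 0.0897 and 0.151. Without control 3 and control 4, the libraries farthest from the median of the first mean, r was -0.196, so the relation was not seen without the ends of its range, and a correlation tends to be weaker over a narrower range. The unadjusted Pearson p met the criterion stated for this hypothesis, but it does not survive adjustment, and the difference of both means did not separate the groups (exact permutation p = 0.514). A time-of-day effect could therefore neither be shown nor excluded.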
